A study of Mus musculus with 24 samples.

How the data were processed

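The series profiled chromatin by ChIP-seq in mouse C57BL/6 bone marrow cells: granulocyte-monocyte progenitors (GMP, the normal myeloid progenitor population), leukemia stem cells (LSC) and mature acute myeloid leukemia cells (mAML). The leukemia cells carried the MLL-AF10 fusion, per the labels' protocols. The 24 samples fell into 2 parts. In the first, each of the 3 populations had 4 libraries: H3K27ac, H3K4me1, H3K4me3 and input. In the second, LSC were sampled at 0, 24, 48 and 72 hours of A-485, an inhibitor of the p300 and CBP acetyltransferases, with H3K27ac, P300 and input libraries at each of the 4 time points. Each group held 1 sample, so the series had no replicates. The titles of 4 libraries of the second part name H2K27ac while their antibody field names H3K27ac; the antibody field was followed.

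Chromatin was indexed and pooled before immunoprecipitation, per the labels' protocols. Such pooling lets several libraries share an antibody reaction. The submitters' processing notes name BWA (an aligner), Picard, MACS2 (a peak caller), HOMER and deepTools, and the genome build mm9. Their order, settings and versions are not given in the sources used here, nor are the rule by which a region was called an enhancer and the marks that entered it.

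The values analysed here were 6 region lists that the authors deposited for the whole series. Each list gave 3 columns (chromosome, start and end) and 0 columns of score, signal or read count, so the depth behind a region is unknown and no threshold could be tightened. The names of 3 lists hold the words enhancer and short with gmp, k+ or k-, and the other 3 are named gained, lost and maintained in tumor. What short refers to is not given in the sources used here, so these lists may not hold all enhancers called. The labels do not define k+ and k-. Surface Kit is commonly used to sort immature from mature blood cells, but whether the names refer to it, and which of LSC and mAML each stands for, is not given in the sources used here. The lists are therefore called by their own names, and k+ and k- together the leukemia lists, since the gained list was found to be built from them. All start and end positions in every list were multiples of 200 bp, and 0 regions touched another region of the same list. No region passed the end of its mm9 chromosome, while 111 gained regions passed the end of the mm10 chromosome. Positions are mm9, counted from 1. Chromosome lengths came from GenomeInfoDb 1.38.1 and chromosome bands from circlize 0.4.16 in R 4.3.3.

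Overlap of at least 1 bp was counted with bedtools 2.31.1 and checked against a count on the 200 bp grid in Python 3.11.15 (NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1; figures with matplotlib 3.10.9). Chance overlap came from 1000 circular shifts of the second list along each chromosome, which keep its clustering. Equal list sizes were made with 1000 random subsets. Regions no more than 12.5 kb apart were stitched into clusters, and the share of regions in clusters of 3 or more was set beside 1000 random placements of the same regions on their chromosomes. Median widths were set beside 10000 random draws from the pooled gained, lost and maintained lists. Shares carry exact Clopper-Pearson 95% intervals. These cover counting error only, and neighbouring regions are not independent, so the intervals are too narrow. Regions are not replicates, and no p-value is given between lists.

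The code was tested on simulated data: in a list of 3329 regions planted to overlap a randomly placed k- list at 40.0% it recovered 40.0%, and an unrelated list of the GMP size overlapped at 0.960% against 0.923% as the mean of its shifts.

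The comparisons, the alternatives and the rule for naming regions were set before the data were examined, except where the text says otherwise. The rule named the 5 widest regions and the 5 clusters with the most regions of the gained, lost and maintained lists. Not among the comparisons set beforehand were loss by region width, lost shares on X and Y, and the windows there. Leukemia regions with against without a GMP partner were not among them either. The alternatives covered the minimum overlap, the region definition, a width minimum in place of a score, the chance model, list sizes, the stitching distance and the chromosomes used. Lists of genes and of sequence motifs had also been set, for use with an mm9 annotation and genome only. The gene table at hand was for GRCm38, coordinates were not converted between builds, and genes near regions, promoter distance and motifs were not analysed here. Read signal of the 24 libraries, and with it the A-485 time course and P300 occupancy, was not analysed here.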

Results

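Enhancer catalogues of normal granulocyte-monocyte progenitors (GMP) and of MLL-AF10 leukemia cells were compared to ask which candidate enhancers the leukemia gained, lost or kept relative to its normal counterpart, and how the leukemia lists differed from each other. H3K27ac and H3K4me1 are the histone marks by which active and primed enhancers are usually recognised, and H3K4me3 marks promoters. The data were 6 lists of regions on mm9 with no score and no read counts, so the depth behind each region is unknown. No list had a replicate, and the comparisons therefore describe these lists.

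The leukemia lists were longer and covered more of the genome than the GMP list. The GMP list held 3332 regions covering 2.41 Mb. The k+ list held 9404 regions covering 10.4 Mb, which was 2.82 times as many regions and 4.31 times the length. The k- list held 13856 regions covering 16.9 Mb, which was 4.16 times as many regions and 7.01 times the length of the GMP list, and 1.47 times as many regions as the k+ list. Leukemia regions were also wider. The median width was 600 bp in the GMP list (quartiles 400 and 1000 bp) and 800 bp in both leukemia lists, with an upper quartile of 1400 bp in k+ and 1600 bp in k-. Regions of 1000 bp or more made up 26.2% of the GMP list, 43.9% of k+ and 48.5% of k-. The widest region of the GMP list measured 7200 bp, against 11600 bp in k+ and 17000 bp in k-.

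The gained, lost and maintained lists followed from the 3 enhancer lists. Merging k+ and k- gave 16869 leukemia regions. All 15189 of these that met no GMP region by 1 bp were, with identical coordinates, the gained list. All 1504 GMP regions that met neither leukemia list were the lost list. The other 1828 GMP regions met a leukemia region, and the maintained list was their intersection with the leukemia regions, in 1870 pieces covering 1.29 Mb. Thus 90.04% of leukemia regions (95% interval 89.6 to 90.5%) were outside the GMP catalogue, and 45.1% of GMP regions (43.4 to 46.8%) were without a leukemia partner. The first share rests largely on list length. With 16869 leukemia regions and 3332 GMP regions, most leukemia regions would count as gained even if every GMP region met a different one. How far calling depth set the short GMP list is unknown. A single overlapping base pair decided these classes. When at least 50% of both regions had to be shared, 443 GMP regions were met and 2889 were not.

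Gained regions lay on every autosome and X, and many sat in dense domains. Of the 15189 gained regions, 42.0% lay in clusters of 3 or more regions stitched at the distance given with the methods, against a mean of 1.88% and a maximum of 2.495% over 1000 random placements. The domain with the most gained regions was on chromosome 2 in band qH3, from 169968801 to 170050400, where 21 gained regions lay within 81.6 kb. The span also held 5 GMP regions, and 16 k+ and 16 k- regions lay in it. On chromosome 17 in band qB3, from 44806601 to 44869400, 15 gained regions lay beside 3 GMP regions. Other gained domains held no GMP region at all. On chromosome 9 in band qB, 15 gained regions lay between 55082001 and 55157400. On chromosome 18 in band qD3, 14 gained regions covering 26800 bp lay between 55062201 and 55144200. The fifth, on chromosome 3 in band qD from 60271601 to 60341200, held 14 gained regions. In its span lay 6 k+, 13 k- and 1 GMP region. The widest gained region covered 11000 bp of chromosome 19 in band qD2, from 58189801 to 58200800, and the next in width lay on chromosomes 14, 15, 2 and 10 and measured between 10000 and 10800 bp.

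Lost regions were narrow, and their densest groups lay in a few places. The 5 clusters with the most lost regions were on chromosomes 11, X and Y. The first, on chromosome 11 in band qA1 from 3037001 to 3090000, held 15 lost regions and lay close to the lowest position that any list reached on an autosome, 3004801. It fell in the largest GMP cluster, of 22 regions covering 38000 bp within 63 kb. How well reads map there was not examined, so this group may not be a domain of enhancers. On X in band qE3, 13 lost regions lay from 120741601 to 120784800, 9 from 120117001 to 120129400 and 8 from 121298401 to 121311800. On Y in band qA1, 12 lost regions lay from 2847801 to 2901600, including the widest lost region, of 7200 bp. In all, 10.9% of lost regions lay in clusters of 3 or more, against a mean of 0.0271% over random placements. On autosomes alone the share was 5.48%.

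Maintained regions lay in groups of at most 7 pieces, in a list far shorter than the gained list. Their share in clusters of 3 or more was 13.9%, against a mean of 0.0286% over random placements. The cluster with the most, 7 pieces on chromosome 11 in band qA1 from 3027001 to 3060000, overlapped the lost cluster named above, and this span held 8 k- regions and 1 k+ region. The limit on mapping given for the lost cluster holds here too. The next, on chromosome 8 in band qC3 from 86716001 to 86746400, held 6 maintained pieces within a span of 7 GMP, 5 k+ and 7 k- regions. The widest maintained piece was 4400 bp on chromosome 7 in band qA3, from 29167201 to 29171600, within the second widest GMP region. The clustered share rests on list length: drawn down to the 1504 regions of the lost list, 1.36% of gained and 10.001% of maintained regions lay in such clusters. Thinning a list lowers this share by itself, so the lists are not ranked by it.

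The median width was 800 bp for gained, 400 bp for lost and 400 bp for maintained regions. In 10000 random draws from the 3 lists together, the median of a list of the gained size was 600 bp throughout, and that of lists of the lost and maintained sizes lay between 600 and 800 bp. Most of this pool is the gained list itself, so draws of its size could hardly vary. Gained regions are also merged from k+ and k-, which widens them, so the draws add no independent weight to the order of widths. Maintained pieces are intersections; the whole GMP regions behind them had a median of 600 bp. Width went with loss. On autosomes, 60.4% (56.8 to 64.0%) of the 728 GMP regions of 200 bp had no leukemia partner, against 37.0% (33.0 to 41.2%) of the 551 regions of 800 to 1000 bp and 12.04% (6.57 to 19.7%) of the 108 regions of 2200 bp or more. Under 200 circular shifts, 99.2% of the regions of 200 bp and 97.5% of those of 2200 bp or more were without a partner on average.

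**Figure D1:**
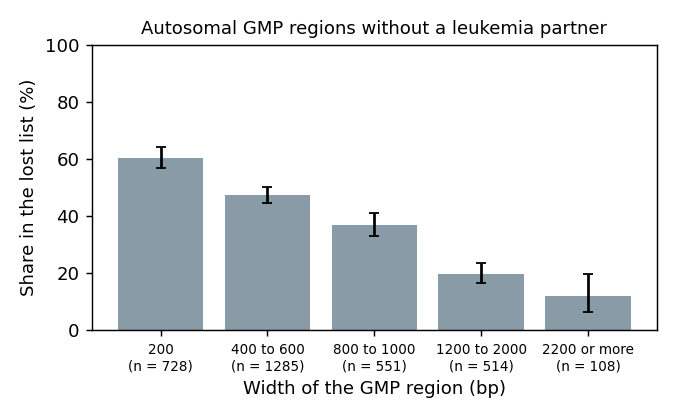
Share of autosomal GMP regions that are in the lost list (y axis, percent) by the width of the GMP region (x axis, bp); bars show the share and error bars its exact 95% interval, with the number of regions under each bar. The share is 60.4% at 200 bp and 12.04% at 2200 bp or more.

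The catalogues overlapped far more than their placement by chance. Of the GMP regions, 37.8% (36.1 to 39.4%) met a k+ region, against a mean of 0.587% and a maximum of 1.26% over 1000 circular shifts. For k- the share was 47.4% (45.7 to 49.1%), against a mean of 0.926% and a maximum of 1.77%. Of the k+ regions, 61.0% (59.97 to 61.95%) met a k- region, and 39.5% (38.6 to 40.3%) of k- regions met a k+ region, with shift means of 1.15% and 0.770%. None of the 1000 shifts reached an observed value in any of these comparisons. The shifts run over whole chromosomes and ignore where regions can be mapped or tend to lie. Lists of regions crowded into the same stretches may exceed them, so the excess does not by itself show how closely the cells are related. In base pairs, k+ and k- shared 6.39 Mb, or 30.7% of their union, and GMP shared 7.28% of the union with k+ and 6.06% with k-. A short list can fill only a small part of a union, so these shares are not comparable between pairs. Of the base pairs of the shorter list, 61.7% of k+ lay in k-, 36.0% of GMP in k+ and 45.8% of GMP in k-. These shares also depend on the length of the other list. With all lists drawn at random to 3332 regions, 13.6% ± 0.538 (SD over 1000 subsets) of GMP regions met k+ and 11.6% ± 0.540 met k-. Random thinning lowers each share about in proportion to the regions removed, so this order follows from the list lengths and the overlaps of the whole lists, and k+ and k- are not ranked by it. With the widest regions kept at equal sizes, the shares were 26.0% for k+ and 28.6% for k-. When 50% of both regions had to be shared, 11.5% of GMP regions met k+, 12.515% met k- and 31.8% of k+ regions met k-.

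Gained regions were divided between the leukemia lists, and most were in 1 of them only. Of the gained regions, 28.3% (27.6 to 29.0%) met both lists, 21.2% (20.6 to 21.9%) met k+ only and 50.5% (49.7 to 51.3%) met k- only. Those in both lists had a median width of 1800 bp, against 400 bp for k+ only and 600 bp for k- only. Gained regions are merged from both lists, so joining widens those in both, and a wide region has more room to meet both. Among the 1828 GMP regions met in leukemia, 55.3% (52.9 to 57.5%) met both lists, 13.6% met k+ only and 31.2% met k- only. The split of gained regions depends on list length and on the overlap asked for: with k- drawn down to the size of k+, 36.9% met k+ only and 40.2% met k- only, and with 50% of both regions shared, 16.8% met both.

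**Figure D2:**
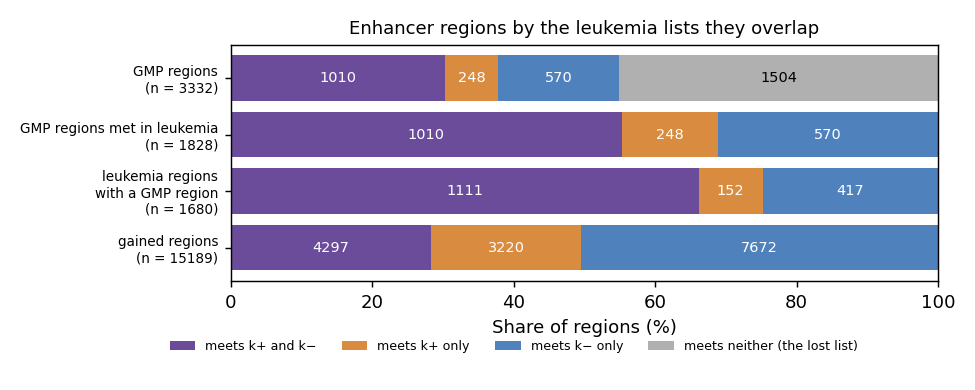
Share of regions (x axis, percent) that overlap both leukemia lists, k+ only, k- only or neither, for all GMP regions, the GMP regions met in leukemia, merged leukemia regions with a GMP region, and gained regions; numbers in the bars are regions. Overlap with both lists takes 66.1% of leukemia regions with a GMP region and 28.3% of gained regions, without matching of widths.

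Leukemia regions that coincided with a GMP region were more often shared by both leukemia lists. Of k+ regions with a GMP region, 84.8% (82.7 to 86.9%) also met k-, against 57.6% (56.5 to 58.6%) of k+ regions without one. Of k- regions with a GMP region, 70.2% (67.8 to 72.6%) also met k+, against 35.8% (35.005 to 36.701%) without one. Regions with a GMP partner were wider, with medians of 1600 against 600 bp in k+ and 1800 against 800 bp in k-. Against regions without a GMP partner drawn to the same widths, the difference shrank from 27.3 to 10.2 percentage points for k+ and from 34.4 to 12.2 for k-, and the observed shares stayed above all 1000 draws (71.2 to 78.6% for k+, 54.4 to 61.5% for k-). Of merged leukemia regions with a GMP region, 66.1% met both lists, against 28.3% of gained regions. For those whose width was found among gained regions the share was 65.9%, against a mean of 57.6% (54.6 to 60.4% over 1000 draws) for gained regions drawn to the same widths. This comparison was not among those set beforehand, and the matching was added after the data had been seen.

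The chromosomal make-up of the lists differed mainly on the sex chromosomes, and on X through 1 window. X held 105 of 3332 GMP regions, or 3.15% (2.58 to 3.80%), against 1.16% (0.953 to 1.40%) of k+ and 1.49% (1.29 to 1.70%) of k- regions. Y held 41 GMP regions, or 1.23% (0.884 to 1.67%), and 0 regions of both leukemia lists, which allows a share of up to 0.0392% in k+ and 0.0266% in k-. Of the 105 GMP regions on X, 95 were lost, or 90.5% (83.2 to 95.3%), and all 41 on Y were lost, against 1368 of 3186 on autosomes, or 42.9% (41.2 to 44.7%). Among autosomes, the intervals of GMP and leukemia lists were apart for chromosome 9 alone, with 4.50% (3.82 to 5.26%) of GMP and 5.72% (5.34 to 6.12%) of k- regions. The k+ and k- lists were apart on none of the 21 chromosomes. On X, 60 of the 105 GMP regions lay in a window of 2.73 Mb in band qE3, from 120117001 to 122846800, in which k+ and k- held 0 regions. Outside the window, X held 45 of the 3332 GMP regions, 109 of the 9404 k+ regions and 206 of the 13856 k- regions. The higher X share of the GMP list thus came from this window. On Y, the 41 regions lay within 1.64 Mb, from 1262201 to 2901600.

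**Figure D3:**
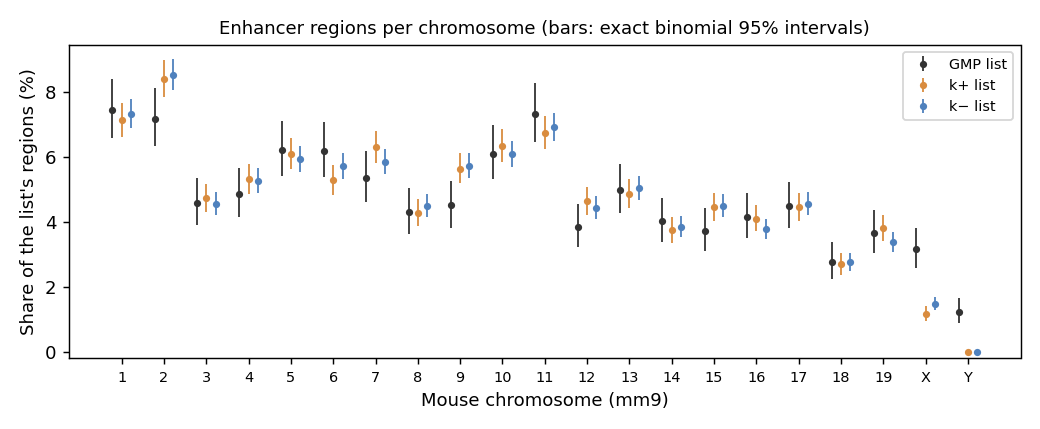
Share of each list's regions (y axis, percent) on each mouse chromosome (x axis, mm9) for the GMP, k+ and k- lists; points are shares and bars exact 95% intervals. The GMP list stands above the leukemia lists on X (3.15% against 1.16 and 1.49%) and Y (1.23% against 0). On X, 60 of its 105 regions lie in 1 window of 2.73 Mb, and the excess comes from that window.

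**Figure D4:**
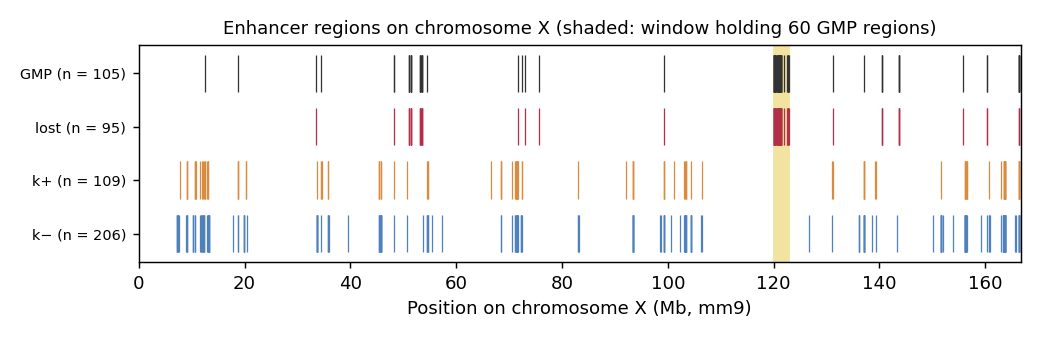
Positions of regions on chromosome X (x axis, Mb on mm9) in the GMP, lost, k+ and k- lists, each region drawn as 1 tick. The shaded window holds 60 of the 105 GMP regions, all of them lost, and 0 regions of k+ and k-.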

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

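As no list had a replicate, leaving out a replicate was not applicable, and counts of genes near regions and of sequence content under other settings were not run, since an mm9 annotation and genome were not used here. No paired analysis was possible because each group has 1 sample. The autosomal values other than regions per list, gained regions by list and median widths, the removal of the chromosome 11 span, whole GMP regions for the maintained list, the gap in GMP overlap at equal sizes and both alternatives for leukemia regions with a GMP partner were added after the data had been seen. Of 101 alternative values, most were single counts, shares or widths, which have no direction to turn. For chance overlap and clustering of the GMP, k+ and k- lists, 10 were classed as moved and 5 as the same. For the other results, 48 were classed as moved and 37 as the same. A direction could turn only for the gap in GMP overlap and the excess of shared regions with a GMP partner. It turned for 1 value: GMP overlap was 9.66 percentage points higher with k- than with k+, and -1.95 points at equal list sizes. This turn follows from random thinning, which removes more of the longer k- list. That gap was 1.02 points at 50% of both regions and 2.64 points with the widest regions at equal sizes. Asking for 50% of both regions lowered the share of GMP regions met by k+ to 11.5% and by k- to 12.515%, and of k+ regions met by k- to 31.8%; it left 443 GMP regions met and 2889 lost, or 86.7%. Within 1 kb these shares were 49.9%, 62.2% and 70.1%, with 31.6% of GMP regions lost. Regions cut to 500 bp either side of their midpoint gave 45.1% for GMP in k- and 57.1% for k+ in k-. Keeping regions of at least 800 bp, the median width, left 1223 GMP, 5008 k+ and 7977 k- regions and gave overlaps of 43.0%, 55.2% and 69.6%. At equal sizes the widest regions gave 26.0% and 28.6% for GMP in k+ and k-, and 55.0% for k+ in k-. On autosomes GMP overlap with k- was 49.3% and 42.9% of GMP regions were lost, or 42.8% when the chromosome 11 span was also left out. Gained regions at 50% of both regions were 24.6% k+ only, 58.6% k- only and 16.8% both, and with k- drawn down to the size of k+ they were 36.9%, 40.2% and 22.9%. Joining regions within 1 kb raised the median width to 1000 bp for gained and 600 bp for maintained regions, and whole GMP regions gave 600 bp. Stitching at 5 kb put 22.2% of gained, 8.24% of lost and 7.33% of maintained regions in clusters of 3 or more, and at 25 kb 58.4%, 14.2% and 19.2%. Drawn down to the shortest list, the gained and maintained shares were 1.36% and 10.001%, by construction of a thinner list, and on autosomes the lost share was 5.48%. The excess of shared regions among those with a GMP partner was 10.2 points in k+ and 12.2 in k- at matched widths, and 20.4 and 21.5 points at 50% of both regions. The lists hold no scores, so how far calling depth set their lengths was not tested.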

Other observations

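All tests in this part were chosen after the results they bear on had been seen, except the comparisons at matched widths on X and at matched widths and neighbour numbers, whose outcome had not been seen when they were chosen. The counts within 1 kb and of regions of 800 bp or more, used below for the lengths of k- and k+, had been set before the data were examined, and only their use as tests was chosen afterwards.

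Some loci held regions of 1 leukemia list alone. Counting only regions more than 1 kb from the other list, k+ had 2816 such regions and k- had 7441. On chromosome 16 in band qB3, from 33769601 to 33796800, 7 k+ regions lay beside 4 GMP regions and 0 k- regions. On chromosome 5 in band qE5, from 104193601 to 104217400, 4 k+ regions lay with 0 k- and 0 GMP regions, as did 4 on chromosome 18 in band qB2, from 36319401 to 36327800. For k-, 9 regions lay on chromosome 10 in band qB4 from 59714801 to 59747400, with 0 k+ and 0 GMP regions. On chromosome 6 in band qF3, from 129283601 to 129311400, 8 k- regions lay with 1 GMP and 0 k+ regions, and on chromosome 17 in band qA3.3, from 28831601 to 28847800, 7 k- regions covered 10800 bp with 1 GMP and 0 k+ regions. Among the 5 clusters with the most such regions in each list, these were the ones with 0 regions of the other list in their span; the others held 1.

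Of whole lists, 12.4% (11.8 to 13.1%) of the k+ regions and 10.5% (10.01 to 11.04%) of the k- regions met a GMP region. Among regions shared by both leukemia lists the share was 17.3% (16.3 to 18.3%) in k+ and 18.7% (17.7 to 19.8%) in k-, and among regions of 1 list alone it was 4.82% (4.15 to 5.57%) in k+ and 5.17% (4.71 to 5.67%) in k-. The intervals overlap in both classes, and the classes are not matched on width: median widths were 1200 bp in k+ and 1600 bp in k- for shared regions, and 400 and 600 bp for regions of 1 list alone. The k- list had more regions of its own, 60.5% of it against 39.0% of k+.

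Lost regions lay near leukemia regions more often than in a random placement. On autosomes, 447 of 1368 lost regions, or 32.7%, lay within 1 kb of a leukemia region, against 2.34% in 1 random placement. The median distance was 6600 bp against 207400 bp. Of gained regions, 4.44% lay within 1 kb of a GMP region and 20.0% within the stitching distance used for clusters, against 0.467% and 2.69% in 1 random placement. A random placement ignores where along chromosomes regions can be mapped or tend to lie. Any lists crowded into the same stretches would exceed it, so these values show nothing particular to lost or gained regions.

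GMP regions on X and Y were lost more often than those on autosomes. The tables argue against a pair of explanations of the X excess as its whole cause. One window of X is not enough: outside it, 35 of 45 GMP regions, or 77.8% (62.9 to 88.8%), were lost, above the autosomal 42.9% (41.2 to 44.7%). Narrow regions on X are not enough, since autosomal rates at the same widths would give 44.2% where 90.5% were lost. A few local groups on X stay open, however: 23 of the 35 lost regions outside the window lay in bands qA5 (16 of 18 GMP regions lost) and qF2 (7 of 7), and of the other 20 GMP regions 12, or 60% (36.1 to 80.9%), were lost, an interval that holds the autosomal share. These bands were picked for holding the most lost regions, which lowers the share of the rest, so this value does not decide. The absence of Y regions, where the GMP share would give 116 in k+, is what leukemia libraries with no Y chromosome would show. It is also the observation to be explained. The X window likewise held 0 k+ regions where the GMP share would give 169, although k+ held 109 regions elsewhere on X. A count of 0 over a local group thus does not by itself show a missing chromosome. No list held a region on Y outside the 1.64 Mb span, however, and how much of Y can be mapped was not examined. Whether the Y regions are a local group like the X window is therefore unknown. Donors of another sex or loss of Y may lie behind the Y part, but the labels used here give no sex. A copy number or mapping difference private to the GMP libraries stays open for both X and Y.

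The k- list was longer than the k+ list. If k+ were a shallower call of the same regions, nearly all k+ regions might be expected to lie by a k- region. Of k+ regions, 70.1% (69.1 to 71.0%) lay within 1 kb of one. Without replicates, the share that repeated calls of the same regions would reach is unknown. The k+ regions that met no k- region were also narrow, with a median of 400 bp against 1200 bp for those that did. This value therefore does not decide whether k+ was a shallower call. An excess of narrow k- regions is not enough, as k- was 1.59 times as long among regions of 800 bp or more. A difference in depth and a difference between the cells behind the lists may each account for part, and no value in these lists separates them.

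Leukemia regions with a GMP partner were more often shared by k+ and k-. Wider regions account for part of this, but a difference of 10.2 percentage points stayed for k+ at matched widths, with 84.8% (82.6 to 86.8%) against draws of at most 78.6%. Wider regions in denser neighbourhoods are not enough either, since at matched widths and neighbour numbers the difference was 10.3 percentage points, with 84.3% (82.1 to 86.4%) against draws of at most 77.4%. Signal strength, which these lists do not hold, is a further candidate explanation and was not tested.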
